A study of Mus musculus with 11 samples.

How the data were processed

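RNA from the left atrial appendage of 11 adult male mice of the FVB strain was hybridised to Illumina mouse expression arrays, 1 array per mouse. All mice received tamoxifen for 4 days and were killed on day 5. Per the labels' protocols, total RNA was amplified into biotin-labelled cRNA. The control group held 6 mice that carried Myh6MCM only. The TBX3-induced group held 5 mice that carried Myh6MCM together with CTBX3. MCM is read here as the tamoxifen-inducible MerCreMer recombinase under the heart muscle Myh6 promoter, which is background knowledge and not a statement of the labels. Groups and mouse numbers were taken from the sample titles.

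The values used were the authors' processed values, deposited as 1 log2 value per probe and array for 45281 probes. The background correction, the normalization and the software behind them are not given in the sources used here, and neither is the log base. Base 2 was taken because the highest deposited value, 15.4, then lies within the range of an array scanner. The deposited medians per array lay between 4.39 and 4.45 and the upper quartiles between 6.48 and 6.57. The arrays were thus on a similar scale as deposited, and how this came about is not given. The values were rounded to 2 decimals, were not centred per gene, and 128 of them were below 0. A second table held non-normalized signals with detection p-values under column names that match no mouse. Its 22 columns of per-sample values could not be tied to mice by name and were not used in any step. A match by their values was not tried. The analysis planned before the data were examined started from those signals (limma's neqc with a detection filter). It was replaced by the same model on the processed values. The alternatives without background correction, and with neqc and a common 75th percentile from the signals, were not run, since those columns were not tied to mice. The alternative with the array chip as a block was not run, since chip identities are not given in the sources used here.

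Probes were named from the platform annotation. Of all probes, 34885 had 1 gene symbol, 18 had several and 10378 had none there. Gene identifiers of 34807 probes matched the GRCm38.p6 gene table, which changed 0 symbols. In the gene lists 6 older symbols were brought to that table. No coordinates are given, because the build behind the probes is not stated.

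With no usable detection p-values, a floor was set, after the data were examined and before any test, from the 1526 probes of olfactory, vomeronasal and trace amine receptor genes, families used mainly by sensory neurons. The floor was the 99th percentile of their values over all arrays, 4.93 on the log2 scale. A probe was kept if it lay above the floor on at least 5 arrays, the size of the smaller group. Of these receptor probes 10 passed. For each gene the kept probe with the highest mean signal stood for the gene, and probes without a single symbol stayed as features of their own. This left 12741 features, 10208 of them with a gene symbol. Where every array of a group lay at or under the floor, the fold is a lower bound, computed against the higher of the floor and the probe's own value on each array. The number of arrays, not a count of reads, limits the precision.

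Differences are TBX3 induced minus control on the log2 scale. They were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the group as the only term, on all 11 arrays. P-values were adjusted by the Benjamini-Hochberg method over all features, and an adjusted p under 0.05 counts as passing. For the separate Tbx3 probes and for dimmer probes of a gene, the adjustment was over the 18226 probes that passed the filter. Errors of differences are the moderated standard errors (SE), and spreads within a group are standard deviations (SD) over 5 or 6 mice. On simulated data with the features' own means and spreads, 47.8% of genes changed by 0.5 on the log2 scale, 89.6% of those changed by 1 and 98.5% of those changed by 2 were recovered among 12741 features, and 3.7% of the calls were false. The simulation was 1 draw of independent features, with 200 of them changed and the same spread in both groups. The real arrays differ in these respects, so the rates check the method and do not estimate errors in these data.

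Before the data were examined 30 gene lists were fixed, of which 26 had at least 5 measured members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation 0 of the 26 lists were called by camera, and 2 had an unadjusted p under 0.05. Fry, which tests whether a list's genes move one way on balance without reference to other genes, called 7 lists. An exact two-sided permutation test of the list means per mouse over all 462 splits of the mice, adjusted over the lists, was added after the data were seen. Its smallest possible p is 0.00216. It called 7 lists, of which camera also called 5.

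Genes were named by a rule fixed before the data were examined, and others are said to be chosen after their values were seen. Some genes of its panel are not reported here. The rule took a panel of 20 genes, the 10 largest rises and 10 largest falls among passing genes with all 5 induced mice on the same side of the control mean, and up to 4 members of each list with the smallest adjusted p. Alternatives changed the floor, the filter, the collapse to genes, array weights, the variance prior, the scaling between arrays, a block for the mouse number, and left out each mouse in turn.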

Results

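Expression was measured in the left atrial appendage of 5 mice in which the T-box transcription factor TBX3 was induced in heart muscle by tamoxifen, and of 6 tamoxifen-treated controls that carried the recombinase alone. TBX3 is known as a regulator of the cardiac conduction system, including the sinus node. The comparison asks which atrial genes differ after short induction of the factor in adult atrial muscle. On each array 39.06% to 39.92% of the probes lay above the floor. The mean correlation of a control with the other controls was 0.976 to 0.985 across features. The mean correlation of an induced mouse with the controls was 0.909 in mouse 1, 0.945 in mouse 6, 0.961 in mouse 3, 0.97 in mouse 4 and 0.981 in mouse 2. The first principal component held 58% of the variance. Induced mouse 1 stood farthest along it, at 74.8, and induced mouse 2 at -15.4 lay near the controls, which spanned -30.2 to -20.5.

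Tbx3 itself was read by 4 probes, which did not move together. Probe ILMN_3061990 was under the floor in all 6 controls, at 4.42 ± 0.11 (SD, n = 6), and reached 8.18 ± 0.81 (SD, n = 5) in the induced mice. This was at least 9.54-fold higher (limma adjusted p = 4.88e-05), and an exact permutation test gave p = 0.00216, the smallest it can give. Its signal was 9.18 in induced mouse 1, 7.38 in mouse 2, 7.31 in mouse 3, 8.43 in mouse 4 and 8.62 in mouse 6, so every mouse labelled as induced carried the signal and no control did. Probes ILMN_1247220 and ILMN_3139514, above the floor on all arrays, fell. The first went from 6.76 ± 0.18 to 5.97 ± 0.36, which is 1.73-fold lower (adjusted p = 0.00727), and the second from 6.00 ± 0.39 to 5.28 ± 0.19, which is 1.65-fold lower (adjusted p = 0.0172). The fourth probe was under the floor on every array. Which of these probes match the transgene is not given in the sources used here. ILMN_3061990 was singled out after the values of all 4 were seen, and ILMN_1247220, the brightest, stands for Tbx3 in the counts over all features, where it is among the lower ones.

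**Figure D1:**
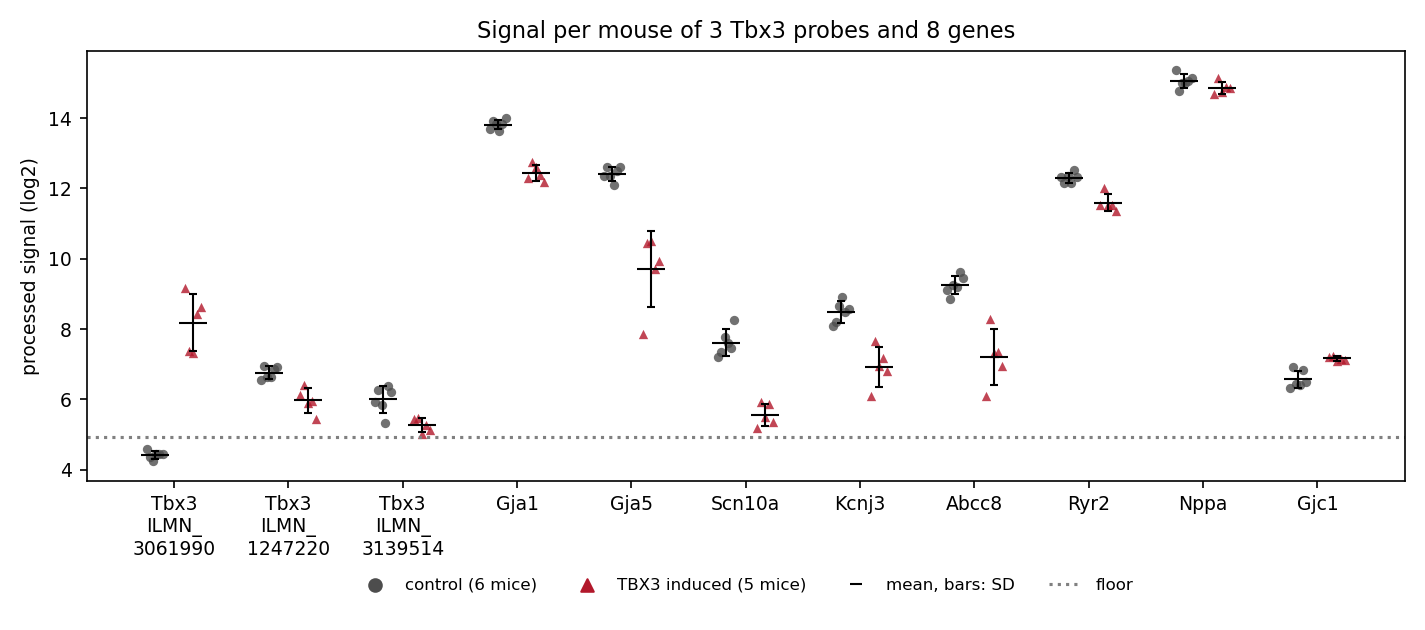
Processed log2 signal (vertical axis) of 3 Tbx3 probes and 8 genes in each control mouse (grey circles) and each TBX3-induced mouse (red triangles). Black marks are group means with SD bars, and the dotted line is the floor at 4.93. Probe ILMN_3061990 lies between 7.31 and 9.18 in the 5 induced mice and under the floor in every control.

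Of 12741 features, 2952 (23.2%) differed between the groups, 1514 of them higher and 1438 lower in the induced mice. By at least 2-fold, 239 were higher and 315 lower. The largest falls by the naming rule were in Inmt, an N-methyltransferase (32.5-fold lower, log2 change -5.02 ± 1.06 SE, adjusted p = 0.00947), Phkg1, the muscle catalytic subunit of phosphorylase kinase (13.1-fold lower), Gm14685 (9.97-fold lower), and Bmp3, a secreted protein of the BMP family (9.90-fold lower, log2 change -3.31 ± 0.38, adjusted p = 0.000481). They were followed by Lamb3, a laminin chain, at 8.54-fold, Cilp2 at 8.49-fold, Rd3l at 8.38-fold, the ADP-ribosyltransferase Art5 at 8.02-fold, Doc2g at 7.86-fold and the RNA helicase Mov10l1 at 7.80-fold lower. Induced means of Gm14685 (4.89) and Bmp3 (4.18) lay under the floor, so the sizes of their folds are uncertain. The largest rises were in Acta1, skeletal muscle alpha-actin (13.7-fold higher, log2 change 3.78 ± 1.02, adjusted p = 0.0238), Nmrk2, a nicotinamide riboside kinase (log2 change 3.47 ± 0.43, adjusted p = 0.000682), and Aldh1a3, an enzyme of retinoic acid synthesis (10.2-fold, adjusted p = 0.01). Sh2d2a was at least 5.16-fold higher and Slc1a2, a glutamate transporter, at least 4.89-fold higher, since both were under the floor in all controls. Nes, the intermediate filament nestin, was 7.35-fold higher, Lmcd1 7.07-fold, the neurotrophin Bdnf 6.35-fold, Tesc 6.32-fold and the collagen Col8a1 6.23-fold higher. For Nmrk2 a dimmer probe went the other way, with a log2 change of -2.01 ± 0.42 (adjusted p = 0.00925), so its direction depends on the probe. Of the 20 largest changes, 19 passed in each of the 11 fits that left out 1 mouse. The exception was Acta1, which missed the threshold without induced mouse 1 (adjusted p = 0.0518), 3 (0.0545) or 6 (0.0615). Inmt was 4.16 in induced mouse 1 and 11.4 in mouse 2, against a control mean of 12.2, so the size of the largest fall differed widely between mice. Induced mouse 2 lay within the range of the controls for Acta1 (7.83, controls 4.87 to 9.72), Aldh1a3 (5.70, controls 4.61 to 5.92), Nes (6.90, controls 5.86 to 7.31) and Cilp2 (7.94, controls 7.38 to 9.24). Without it the log2 change of Acta1 was 4.68, of Aldh1a3 4.07 (3.35 with all mice), of Nes 3.50 (2.88), of Inmt -6.09, of Phkg1 -4.35 (-3.71), of Cilp2 -3.70 (-3.09) and of Lamb3 -3.68 (-3.09). Without induced mouse 1 it was 2.27 for Nes, -4.28 for Inmt and -3.08 for Phkg1. The counts depended on single mice. Without induced mouse 2 they were 2396 higher and 2482 lower, and without induced mouse 6 they were 557 and 629. Without control 1 the count of higher features was 990, without control 3 the counts were 911 and 942, and without control 5 they were 905 and 922.

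**Figure D2:**
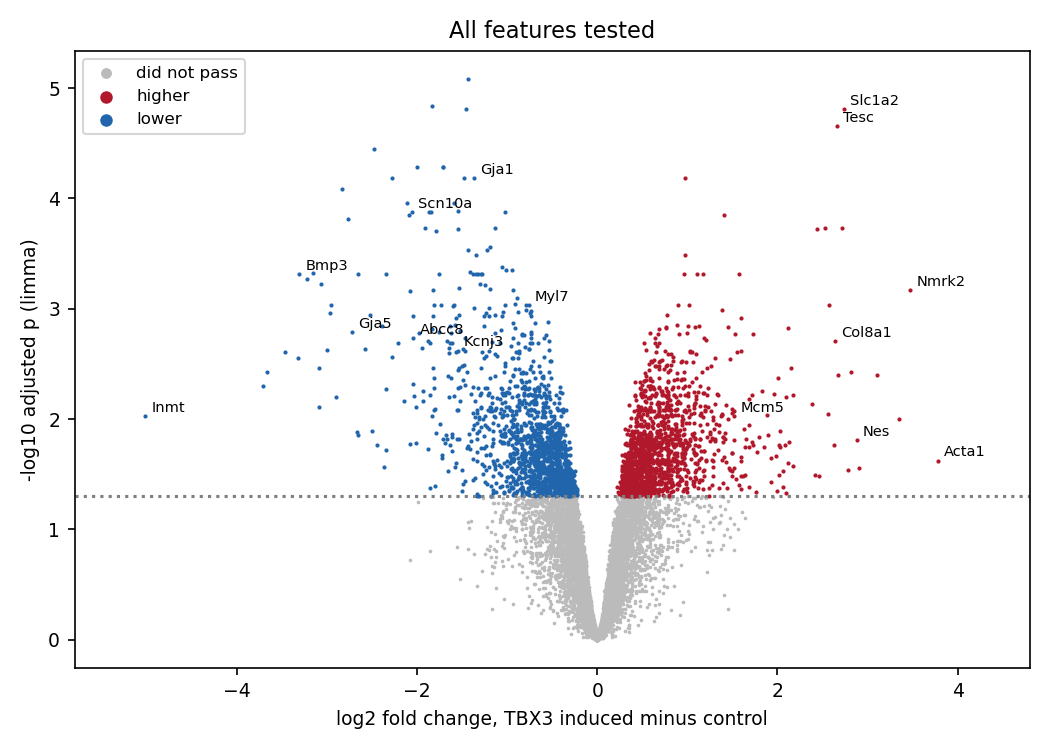
Each point is 1 of 12741 features, with the log2 fold change of TBX3 induced minus control on the horizontal axis and -log10 of the limma adjusted p on the vertical axis. Red points (1514) are higher, blue points (1438) lower, grey points did not pass, and the dotted line marks an adjusted p of 0.05.

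The main connexins of atrial muscle and part of the sodium and potassium channel genes were lower in the induced mice. Gja1 (connexin 43), the main gap junction protein of working myocardium, was 2.59-fold lower (13.82 ± 0.14 in controls, 12.45 ± 0.23 in induced mice, adjusted p = 6.51e-05). Gja5 (connexin 40), the atrial connexin, was 6.60-fold lower (12.42 ± 0.20 against 9.70 ± 1.08, adjusted p = 0.00164). Gjc1 (connexin 45), a connexin of nodal tissue, rose 1.51-fold (adjusted p = 0.00719), and Popdc2, a membrane protein of heart muscle, rose 1.38-fold (adjusted p = 0.0084). Among 15 measured genes of gap junctions and intercalated discs, 5 rose and 3 fell, and 7 did not pass (the counts were 5 and 3 when adjusted over the list alone). The gap junction list did not pass (median 0.01, or -0.02 to 0.09 without 1 mouse, mean -0.05, camera direction up, adjusted p = 0.854).

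Of 6 measured sodium channel genes, 3 fell and 0 rose (5 and 0 adjusted over the list alone). Scn10a, a voltage-gated channel subunit, was 4.16-fold lower (log2 change -2.06 ± 0.20, adjusted p = 0.000132), Fgf12, a modulator of sodium channels, 2.02-fold lower (adjusted p = 0.00327), and the beta subunit Scn4b 2.53-fold lower (adjusted p = 0.0239). Scn4b missed the threshold without induced mouse 1 (adjusted p = 0.0505) or 6 (0.0651). Scn7a changed by -0.40 (adjusted p = 0.055), and passed without induced mouse 2 (0.0277). The list shifted down (median -0.73, camera adjusted p = 0.00752, but adjusted p = 0.254 with an estimated correlation), and its mean was below the control mean in 5 of 5 induced mice (exact permutation adjusted p = 0.0113). The sodium channel median was -0.26 without the filter on dim probes, and -0.44 at a lower floor, a setting chosen after seeing the data, and camera called the list in both (adjusted p = 0.0226 and 0.00621). Of 19 measured potassium channel genes, 8 fell and 0 rose (9 and 1 adjusted over the list alone). They included Abcc8, the sulfonylurea receptor of atrial ATP-sensitive channels (4.12-fold lower, adjusted p = 0.00183), Kcnv2 (3.64-fold, adjusted p = 0.00599), Kcnj3, a subunit of the acetylcholine-activated channel (2.93-fold, adjusted p = 0.00239), and the background channel Kcnk3 (1.71-fold, adjusted p = 0.00885). Kcnj12, an inward rectifier, was 1.90-fold lower (adjusted p = 0.0226, and 0.0611 without induced mouse 6). Its relative Kcnj2 changed by -0.26 ± 0.20 (adjusted p = 0.346, and 0.0375 without control 6). The potassium channel list shifted down (median -0.58, camera adjusted p = 0.00129, but adjusted p = 0.506 with an estimated correlation, exact permutation adjusted p = 0.0113, below the control mean in 5 of 5 mice). Its median was -0.36 without induced mouse 1 and -0.25 without the filter, and camera called it in both (adjusted p = 0.00148 and 0.00136).

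Of 14 measured atrial chamber genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone). The strongest by p were Myl7, the atrial regulatory myosin light chain (1.69-fold lower, 14.58 ± 0.10 against 13.82 ± 0.19, adjusted p = 0.000931), Gja5, Stard10 (1.94-fold lower, adjusted p = 0.00219) and Kcnj3. Nppa, atrial natriuretic peptide, changed by -0.20 ± 0.11 (adjusted p = 0.214). Its means, 15.06 in controls and 14.86 in induced mice, lay near the highest deposited value. Whether a fall is compressed there was not tested, so the missing call is weak evidence of no change. The T-box factor Tbx5 was 1.34-fold lower (adjusted p = 0.0324), but missed the threshold without induced mouse 1 (0.0547), 4 (0.0645) or 6 (0.0923), or control 2 (0.0548), 4 (0.0601) or 5 (0.0663). The list shifted down (median -0.67, camera adjusted p = 1.71e-05, but adjusted p = 0.464 with an estimated correlation, exact permutation adjusted p = 0.0113, below the control mean in 5 of 5 mice). Over single probes the median of the atrial chamber genes was -1.06. Some of these genes are in other lists too, among them Fgf12 (sodium channels), Kcnj3 (potassium channels) and Gja5 (gap junctions). The falls of these lists are thus not independent. Bmp10 was under the floor on all arrays. Of 12 measured pacemaker and nodal genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone). Rgs6, a regulator of G protein signalling, rose 1.67-fold (adjusted p = 0.00603), Bmp4 rose 2.12-fold (adjusted p = 0.0213), and Vsnl1, a calcium sensor, fell 2.12-fold (adjusted p = 0.00882). Gjc1 is also in this list. The calcium channel Cacna1g changed by -0.12 ± 0.15 (adjusted p = 0.553). The pacemaker channel Hcn4 and the transcription factor Isl1 were read by 1 probe each, under the floor on all arrays. For Hcn4 it read 2.88 in controls and 2.84 in induced mice. The brightest probe of Shox2 exceeded the floor on 4 arrays. The transcripts of these 3 genes were not detected by these probes, or barely so, in either group. Whether the probes respond to their transcripts was not tested. The list as a whole did not pass (median -0.10, or -0.14 to 0.07 without 1 mouse, camera adjusted p = 0.879).

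Of 20 measured calcium handling genes, 4 rose and 4 fell (5 and 6 adjusted over the list alone). Ryr2, the calcium release channel, fell 1.63-fold (adjusted p = 0.00378) and Jph2, which ties it to the cell membrane, 1.38-fold (adjusted p = 0.0163). Casq1, the skeletal muscle calsequestrin, rose 3.11-fold (adjusted p = 0.0179, and 0.0547 without induced mouse 6), and Sri rose 1.28-fold (adjusted p = 0.0226, and 0.066 without induced mouse 6). The calcium handling list did not pass (median 0.02, or -0.03 to 0.04 without 1 mouse, mean 0.00, camera direction down, adjusted p = 0.854). Of 20 sarcomere genes, 3 rose and 6 fell (3 and 7 adjusted over the list alone). Besides Myl7, Tcap fell 1.61-fold (adjusted p = 0.0066) and cardiac troponin I (Tnni3) 1.48-fold (adjusted p = 0.0064), whereas Mybpc3, myosin binding protein C, rose 1.64-fold (adjusted p = 0.0107). The median change was -0.06, or -0.11 to -0.02 without 1 mouse (camera adjusted p = 0.539). Of 21 cardiac transcription factors, 2 rose and 5 fell (4 and 5 adjusted over the list alone). The homeobox gene Prrx1 rose 3.31-fold (adjusted p = 0.00168) and Gata4 1.55-fold (adjusted p = 0.0084). Hopx fell 2.76-fold (adjusted p = 0.00487). Tbx2, the closest relative of Tbx3, fell 1.43-fold (adjusted p = 0.0271), but missed the threshold without induced mouse 1 (0.0542) or 3 (0.0605), or control 2 (0.0505), 3 (0.054) or 4 (0.0511). Nkx2-5 changed by -0.14 ± 0.14 (adjusted p = 0.499). The list of transcription factors did not pass (median 0.12, or 0.07 without induced mouse 3, camera adjusted p = 0.854).

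Most measured genes of extracellular matrix and the cell cycle rose, as did part of the cardiac stress genes. Of 14 stress genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone). They included Tnfrsf12a, a cytokine receptor (5.91-fold, adjusted p = 0.00898), Uchl1 (2.54-fold, adjusted p = 0.0132) and the calcineurin regulator Rcan1 (2.49-fold, adjusted p = 0.0157), besides Acta1. Nppb, brain natriuretic peptide, changed by 0.43 ± 0.34 (adjusted p = 0.363, and 0.049 without induced mouse 2). The list shifted up (median 1.17, camera adjusted p = 0.00807, but adjusted p = 0.685 with an estimated correlation and 0.0566 with fry), and was above the control mean in 4 of 5 mice, all but induced mouse 2 (exact permutation adjusted p = 0.0563). Of 25 extracellular matrix genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone), among them Col8a1, Fbln2, fibulin 2 (2.14-fold, adjusted p = 0.00257), Vcan, versican (2.29-fold, adjusted p = 0.0084), and the collagen VI chain Col6a2 (1.89-fold, adjusted p = 0.00719). The control mean of Vcan, 4.81, lay under the floor, so the size of its fold is uncertain. The list was above the control mean in 5 of 5 mice (median 0.87, camera adjusted p = 1.49e-06, but adjusted p = 0.506 with an estimated correlation, exact permutation adjusted p = 0.0161). Induced mouse 2, at 0.16 above that mean, was below control 6 at 0.20, and the other 4 were above every control. Of 20 cell cycle genes, 16 rose and 0 fell (19 and 0 adjusted over the list alone). The replication helicase subunits Mcm6, Mcm5 and Mcm2 rose 3.19-fold (adjusted p = 0.0112), 2.86-fold (0.00944) and 2.34-fold (0.00599), and cyclin E1 (Ccne1) 1.61-fold (adjusted p = 0.0086). The list was above the control mean in 5 of 5 mice, by 1.55 in mouse 3 and 0.24 in mouse 2 (median 0.97, camera adjusted p = 4.99e-08, but adjusted p = 0.506 with an estimated correlation, exact permutation adjusted p = 0.0161). Control 4, at 0.42, was above induced mouse 2, and the other 4 induced mice were above every control. Of 17 BMP, TGF-beta and WNT genes, 6 rose and 3 fell (6 and 3 adjusted over the list alone). Tgfb3 rose 2.03-fold (adjusted p = 0.00824) and the WNT receptor Fzd2 1.49-fold (adjusted p = 0.00314), whereas Dkk3 fell 2.35-fold (adjusted p = 0.00268) and Tgfb1 1.37-fold (adjusted p = 0.0142). This list did not pass camera (median 0.19, adjusted p = 0.279) but was above the control mean in 5 of 5 mice (exact permutation adjusted p = 0.0113). Its median was 0.12 without the filter, 0.09 over single probes and 0.08 without control 3 or 5.

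**Figure D3:**
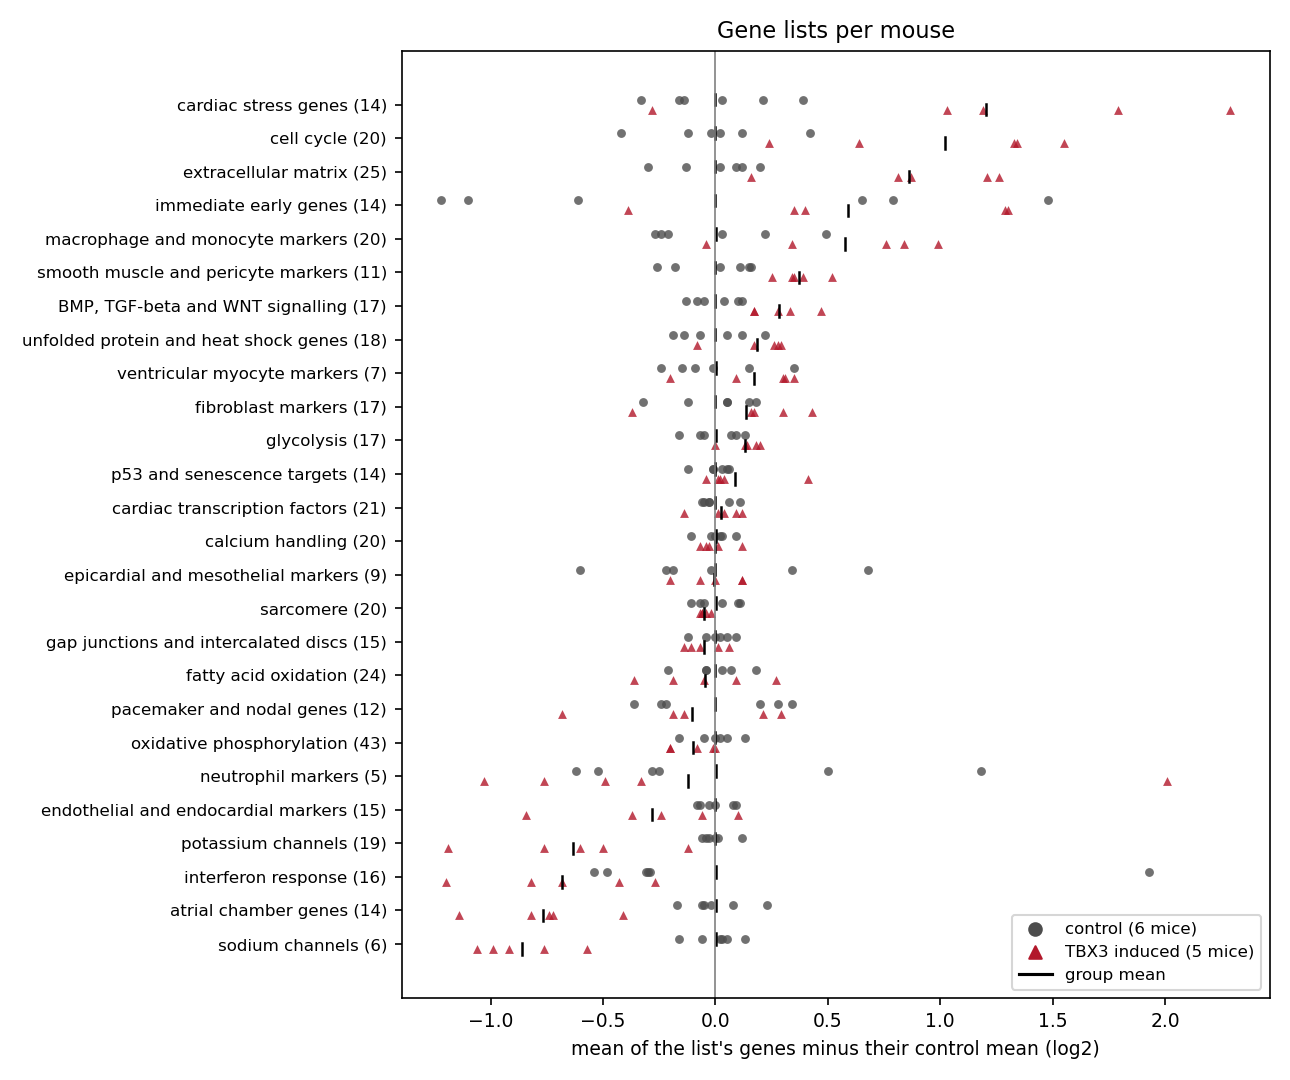
Mean over the measured members of each gene list (their number in parentheses) minus the control mean, on the log2 scale (horizontal axis), for each control (grey circles) and TBX3-induced mouse (red triangles), with black bars for group means. The lists of sodium channels, potassium channels and atrial chamber genes lie below the control mean in 5 of 5 induced mice, and control 4 stands apart at 1.93 in the interferon response list. The atrial list shares Fgf12 with the sodium channel list and Kcnj3 with the potassium channel list.

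Of 20 macrophage and monocyte markers, 3 rose and 0 fell, all 3 chemokines (0 and 0 adjusted over the list alone, with an unadjusted limma p under 0.05 for 6). Ccl2 rose 4.33-fold (adjusted p = 0.025, but 0.0538 without control 3 and 0.0688 without induced mouse 6). Its control mean, 4.34, lay under the floor, so the size of its fold is uncertain. Ccl9 rose 2.54-fold (adjusted p = 0.0424) and Ccl6 2.37-fold (adjusted p = 0.0418). Of the 11 fits without 1 mouse, Ccl9 passed in those without induced mouse 2, induced mouse 4 or control 4, and Ccl6 in those without induced mouse 2 or control 4. In the others the adjusted p reached 0.105 for Ccl9 and 0.0946 for Ccl6. The receptor Csf1r changed by 0.08 (adjusted p = 0.686) and the complement gene C1qa by 0.09 (adjusted p = 0.83); both were chosen after their values were seen. The list shifted up (median 0.39, camera adjusted p = 0.0151, but adjusted p = 0.696 with an estimated correlation, exact permutation adjusted p = 0.0938). Over features above the floor on all 11 arrays, a setting chosen after seeing the data, camera gave an adjusted p of 0.0716, and fry gave 0.139 over the usual features. Of 17 fibroblast markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone). Mfap5, a microfibril protein, rose 3.04-fold (adjusted p = 0.00122), and the receptor Pdgfra changed by -0.43 (adjusted p = 0.0379, passing only without induced mouse 2 among the fits that left out 1 mouse). The fibroblast list did not pass (median 0.02, or -0.10 to 0.18 without 1 mouse, camera adjusted p = 0.756). Of 11 smooth muscle and pericyte markers, 4 rose and 0 fell (6 and 1 adjusted over the list alone), among them Tagln (2.86-fold, adjusted p = 0.0154) and Notch3 (1.42-fold, adjusted p = 0.0154). Camera did not call this list (median 0.43, adjusted p = 0.0986), and the exact permutation test did (adjusted p = 0.0113, above the control mean in 5 of 5 mice). The smooth muscle list also passed camera without the filter (0.0155) or over single probes (0.0142), and passed fry (0.0362). Of 15 endothelial and endocardial markers 1 rose and 0 fell (0 and 0 adjusted over the list alone, with an unadjusted limma p under 0.05 for 8, median -0.32, camera adjusted p = 0.0904). Camera called this list lower over single probes (median -0.35, adjusted p = 0.00659) and without the filter (-0.26, 0.0226), so its call depends on the setting. It was 0.84 below the control mean in induced mouse 1 and 0.10 above it in mouse 2. Flt1, a VEGF receptor, changed by -0.30 (adjusted p = 0.0513, passing without induced mouse 2 at 0.0346 or 4 at 0.0411).

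Of 7 ventricular myocyte markers, 1 rose and 2 fell (2 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.979). That median was 0.13 without induced mouse 6, 0.19 without control 6, 0.25 without induced mouse 1 and 0.14 without the filter. The ventricular light chain Myl2 rose 3.41-fold (adjusted p = 0.0198), most in induced mice 1 (10.06) and 2 (9.51) against a control mean of 6.78, and Hopx and Lrrc10 fell, the latter 2.38-fold (adjusted p = 0.00522). Myh7, the slow myosin heavy chain, changed by 1.31 ± 0.50 (adjusted p = 0.0779, and 0.00592 without induced mouse 2). Neutrophil markers (0 of 5 passed in limma and 1 had an unadjusted p under 0.05, median 0.01, mean -0.12, camera direction down, adjusted p = 0.854) and epicardial and mesothelial markers (0 of 9 and 2 likewise, median 0.01, mean -0.01, camera direction down, adjusted p = 0.954) did not pass as lists. In induced mouse 1 the neutrophil list stood 2.01 above the control mean. Its median was -0.76 without that mouse (adjusted p = 0.154), 0.41 without induced mouse 2 (0.962) and -0.30 with array weights (0.634), so single mice set its size and sign. The epicardial median ran from -0.13 to 0.20 in the fits without 1 mouse. Of 14 immediate early genes, which respond to handling of the tissue, 2 rose and 0 fell (0 and 0 adjusted over the list alone, with an unadjusted limma p under 0.05 for 5, median 0.47, camera adjusted p = 0.101). Their median was 0.22 without control 1 (adjusted p = 0.282), 0.25 without control 3 (0.305), 0.27 without induced mouse 6 (0.199) and 0.31 without induced mouse 1 (0.182). It was 0.76 without induced mouse 2 (0.0788), and camera called these genes higher without control 2 (0.88, 0.0133) or control 5 (0.67, 0.0486). It also did so without the filter (0.0376) and over single probes (0.0274). Lists with fewer than 5 measured members were not tested as lists. Of 4 neuronal and glial genes, Dbh, the noradrenaline-synthesising enzyme, fell at least 1.74-fold (adjusted p = 0.00228) and Cnp 1.39-fold (adjusted p = 0.00933). Of 4 adipocyte genes, Cidea rose 2.01-fold (adjusted p = 0.00755) and Slc36a2 fell 1.27-fold (adjusted p = 0.0291), a call lost without induced mouse 3 (0.0512) or 6 (0.0849), or control 1 (0.0541), 3 (0.0536) or 5 (0.0566). Of 4 erythrocyte genes and 1 lymphocyte gene 0 passed in limma, and the unadjusted p was under 0.05 for Slc4a1 (0.0229) and Alas2 (0.042). All 4 erythrocyte genes passed without control 4 and were lower in the induced mice. The log2 change there was -0.83 for Hbb-b2 (adjusted p = 0.0059), -0.74 for Hba-a1 (0.0185), -1.34 for Slc4a1 (0.0213) and -1.0 for Alas2 (0.022).

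Of 43 genes of oxidative phosphorylation, Ndufv1, a complex I subunit, fell 1.30-fold (adjusted p = 0.0162, and 0.0511 without induced mouse 6), and 0 rose (0 and 0 adjusted over the list alone, with an unadjusted limma p under 0.05 for 7). The list's median was -0.12 (camera adjusted p = 0.0309, but adjusted p = 0.881 with an estimated correlation). Camera missed the threshold without induced mouse 1 (0.0818) or 3 (0.133) or control 3 (0.124), with array weights (0.0518), over single probes (0.0728) or after quantile normalization of the deposited values (median -0.05, adjusted p = 0.225). Fry gave an adjusted p of 0.233, and the exact permutation test did not call it (adjusted p = 0.257). Of 24 fatty acid oxidation genes, 1 rose and 2 fell (0 and 1 adjusted over the list alone), with Cpt1b, the muscle carnitine palmitoyltransferase, 1.43-fold lower (adjusted p = 0.0189, and 0.0526 without induced mouse 6). The fatty acid oxidation list did not pass (median -0.03, or -0.10 to 0.04 without 1 mouse, camera adjusted p = 0.756). Of 17 glycolysis genes, 5 rose and 1 fell (7 and 3 adjusted over the list alone). Pgam1 rose 1.68-fold (adjusted p = 0.00239) and Pfkp 1.83-fold (adjusted p = 0.0144). The median was 0.23, or 0.15 without control 2 (camera adjusted p = 0.0904, and 0.0429 without induced mouse 3 or 0.0487 without control 3). The glycolysis list also passed camera without the filter (0.0328) or over single probes (0.0274), and passed fry (0.0442). Of 18 unfolded protein and heat shock genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.244, and 0.0328 without the filter). Hsp90aa1 rose 2.68-fold (adjusted p = 0.0133) and Herpud1 fell 1.90-fold (adjusted p = 0.011). Of 14 p53 and senescence genes, 3 rose and 2 fell (4 and 4 adjusted over the list alone, median 0.21, camera adjusted p = 0.801). The p53 median was 0.11 without induced mouse 1, 0.11 without the filter and -0.15 over single probes, where its sign turned. Among these genes Phlda3 was 1.57-fold higher (adjusted p = 0.00575) and Sesn1 1.74-fold lower (adjusted p = 0.0113). Of 16 interferon response genes, Rsad2 fell 2.41-fold (adjusted p = 0.01) and 0 rose (1 fell adjusted over the list alone). The list's median was -0.69 (camera adjusted p = 0.0346, but adjusted p = 0.881 with an estimated correlation). Camera missed the threshold without control 4 (median -0.26, adjusted p = 0.142), induced mouse 1 (0.0818) or induced mouse 2 (0.0837), or with array weights (0.141). Fry gave 0.305, and the exact permutation test did not call the list (adjusted p = 0.212). In control 4 the list stood 1.93 above the control mean.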

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

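The tests of explanations in this part, and of the counts under other splits of the mice, were chosen after the results were seen. Among 288 groups of values examined for a mouse far from the rest of its group, 16 had one, and chance gives about 1 in 20, or 14.4. Control 6 had 39.06% of its probes above the floor, and the other controls 39.61% to 39.92%. In induced mouse 1 the neutrophil list stood 2.01 above the control mean, against -1.03 to -0.33 in the other induced mice, and the p53 and senescence list 0.41 above it, against -0.04 to 0.04. In the same mouse Dbh was 3.20 (4.11 to 4.46 in the others), Scn7a 4.60 (5.10 to 5.28) and Cacna1g 4.67 (5.35 to 5.40), all below the floor. In induced mouse 2 Ryr2 was 12.02 (11.37 to 11.54 in the other induced mice), Jph2 11.02 (10.59 to 10.69) and Casq1 5.71 (7.50 to 8.21), each nearer to the controls than in the other induced mice. Among controls, Stard10 was 13.24 in control 5 (12.80 to 12.87 in the others), Kcnj12 8.67 in control 1 (7.65 to 8.02), Prrx1 7.86 in control 2 (6.44 to 6.75) and Ccl6 7.24 in control 4 (5.56 to 6.02). The globin genes were low in control 4, Hba-a1 at 13.78 (14.83 to 15.38 in the other controls) and Hbb-b2 at 6.44 (8.62 to 9.18). The interferon response list stood 1.93 above the control mean in control 4, against -0.54 to -0.29 in the other controls.

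A chance division of the mice is unlikely to explain the counts of changed features, within the limit of the 100 splits drawn. The splits do not address unrecorded differences between the groups. Of 100 splits of the 11 mice into 5 and 6, drawn at random with the real split included, 1 split, the real one, gave as many higher features (1514, highest other 2), and 1, again the real one, as many lower ones (1438, highest other 8). Chance cannot be excluded for the number of gene lists called by camera at the preset correlation, since 21 of the 100 splits called as many (9, highest other 14).

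The Tbx3 probes moved in opposite directions. A single change of Tbx3 RNA read alike by all probes is argued against by the gap between ILMN_3061990 and the mean of the 2 falling probes, which differed by at least 4.01 between the groups with values under the floor set to it (exact permutation p = 0.00216), on probes chosen because they show the pattern. A hypothesis is that ILMN_3061990 reads the transgene and the 2 others may read only the mouse gene, which would then be lower in induced mice. Their mean change was -0.76 (exact permutation p = 0.00433), which this hypothesis allows but does not require. Probe and transgene sequences were not used here, so it stays open whether the 2 probes miss the transgene.

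Myl2, a ventricular light chain, rose in samples of atrial tissue. Ventricular tissue in the induced samples need not raise all of the other 6 measured ventricular markers. In controls Hopx (12.61), Fhl2 (11.77), Myl3 (10.57) and Lrrc10 (9.13) were already brighter than Myl2 (6.78), while Myh7 (5.89) and Hey2 (4.93) were dimmer. The mean change of these 6, -0.09 (exact permutation p = 0.517), is also over members that go both ways and decides nothing. Hopx (-1.47) and Lrrc10 (-1.25) fell, while Myh7 (1.31, adjusted p = 0.0779), Fhl2 (0.46, 0.219), Myl3 (0.39, 0.544) and Hey2 (-0.01, 0.981) did not pass. In induced mouse 2 Myl2 was 9.51 (control mean 6.78) and Myh7 5.38 (control mean 5.89), and in mouse 1 they were 10.06 and 8.74. Ventricular tissue in some samples and a change within atrial muscle cannot be told apart with these values, because the markers move apart, and no biological explanation beyond the induction was tested.

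The interferon response list was called lower in induced mice. A candidate explanation is that control 4 alone held high interferon genes. Without it the list's median went from -0.69 to -0.26 and the camera adjusted p was 0.142. The call was also lost without induced mouse 1 or 2, with adjusted p between 0.0132 and 0.0837 over the fits without 1 of the other mice, so loss of the call alone does not single out control 4. Over those fits the median lay between -0.81 and -0.52, so the size of the shift depended most on control 4. The mean change was -0.682 with all mice (exact permutation p = 0.106) and -0.296 without control 4 (p = 0.127), so a smaller difference between the groups stays open.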

How the results depend on the processing

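The settings with another floor, features above it on all 11 arrays, scaling of the deposited values between arrays and the exact permutation of lists were chosen after seeing the data. No called list changed direction in any setting, and no called named gene did on the probe that stands for it. Only that probe was followed, and other probes of Tbx3, Nmrk2, Myh8 and Actb went the other way. Among the lists not called, the sarcomere median was -0.15 without the filter and 0.02 after quantile normalization of the deposited values, the calcium handling median 0.11 over single probes, the transcription factor median 0.04 without the filter and the fibroblast median 0.21 with array weights. Without a filter on dim probes 808 features were higher and 864 lower of 29453 tested. There 15 of 29 lists were called, 14 of them among the 26 tested with the filter, and the other was that of neuron and glia markers. With the mouse number as a replicate block, which leaves out the control without a partner, 410 were higher and 499 lower. It is not known whether the numbers pair the mice. The correlation of same-numbered deviations was -0.10, -0.15, 0.04, -0.14 and 0.23 for mice 1, 2, 3, 4 and 6, and only mouse 6 correlated best with its own number. The wide spread among the induced mice enters these deviations, so low correlations cannot exclude pairs. In the fit with the block camera also called the endothelial list lower (0.042) and the immediate early genes higher (0.0385), and did not call oxidative phosphorylation (0.101). With an estimated correlation camera called 0 lists. In the remaining settings, with 10786 to 18226 features tested, 1410 to 2117 features were higher and 1228 to 2100 lower. The highest of these counts came with array weights. The weights were 0.25 for induced mouse 1 and 0.39 for induced mouse 2, against 1.08 to 1.53 for the other mice. With 1 mouse left out the counts ran from 557 to 2396 higher, from 629 to 2482 lower and from 7 to 10 lists. The cause of these differences was not tested. Of 101 called genes from the naming rule, 72 passed in each fit without 1 mouse, 82 without the filter and 64 with the block, and 7 of the 9 called lists passed in each fit without 1 mouse. Without the filter Tbx2, Tbx5, Pdgfra, Ndufv1, Slc36a2, Sri, Ccl6 and Ccl9 no longer passed. The fits planned from the scanner signals (no background correction, and neqc with a common 75th percentile) and with the array chip as a block were not run. Signal over the floor limits what is seen: 18226 of 45281 probes passed the filter. Whether changes of the brightest probes are compressed at the top of the scale was not tested.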

Other observations

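The genes in this part were chosen after their values were seen, so their tests describe these mice and are not independent evidence. Among genes of secreted signalling proteins, Edn1, endothelin 1, rose 4.02-fold (log2 change 2.01 ± 0.35 SE, limma adjusted p = 0.00426, higher than the control mean in 5 of 5 induced mice) and passed in each fit without 1 mouse. Hbegf, a growth factor of the EGF family, rose 6.20-fold (log2 change 2.63, and 1.98 without induced mouse 1, adjusted p = 0.017), Tgfb2 4.37-fold (adjusted p = 0.0162) and the pentraxin Ptx3 4.22-fold (adjusted p = 0.0173), each above the control mean in 5 of 5 mice. Induced mouse 2 was below the highest control for Tgfb2 (7.04 against 7.29) and level with it for Ptx3 (5.15). The control mean of Ptx3, 4.62, lay under the floor, so the size of its fold is uncertain. Hbegf, Tgfb2 and Ptx3 missed the threshold without induced mouse 6, at 0.0528, 0.0503 and 0.0517. Inhba, an activin subunit, rose 2.75-fold (adjusted p = 0.0277), a call lost without induced mouse 6 (0.0748) or control 3 (0.057), 4 (0.0502) or 5 (0.0527). All 5 were highest in induced mouse 1 or 6 and lowest among the induced mice in mouse 2.

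In 7 of the 927 called genes with a second probe past the filter, such a probe was called in the other direction. Second probes that were not called were left out of this count, whatever their direction. For Myh8, perinatal myosin heavy chain, the brightest probe fell (log2 change -0.87 ± 0.17, adjusted p = 0.00675), and 2 dimmer probes rose by 3.02 and 2.30 on the log2 scale (adjusted p = 0.000133 and 0.000597). For Actb, often used as a reference gene, the brightest probe rose 1.90-fold (adjusted p = 0.0248), and 2 others changed by -1.02 each (adjusted p = 0.0416 and 0.0425). The call of the brightest Actb probe was lost without control 3 (0.0529), control 5 (0.0503) or induced mouse 6 (0.0717).

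Genes of the daily clock, which follow the hour at which tissue is taken, gave 2 calls among the 6 examined. Nr1d1 was 1.79-fold lower (adjusted p = 0.0156, below the control mean in 5 of 5 mice). Dbp was 3.62-fold lower (adjusted p = 0.0425, below the control mean in 4 of 5 mice), and passed only without induced mouse 2, induced mouse 4 or control 1 among the fits without 1 mouse. Arntl changed by 0.30 (adjusted p = 0.286), Per1 by 0.12 (0.827), Per2 by -0.19 (0.769) and Per3 by -0.81 (0.164, and 0.0158 without induced mouse 2). The hour of tissue collection is not given in the sources used here.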
